A study of Mus musculus with 5 samples.

How the data were processed

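The series holds 5 RNA sequencing libraries of spinal cord from male mice, 3 WT and 2 Lhx1os KO. Per the labels' protocols, tissue was snap frozen and powdered, RNA was extracted with column purification and DNase treatment, and libraries were made with Illumina's TruSeq Stranded mRNA kit, which selects polyadenylated RNA. The deposited values are raw counts of reads per gene, with no normalization, in 1 table over all samples. Per the submitters' processing notes, the authors used cutadapt, Trimmomatic, STAR 2.5.2b, HTSeq and the GRCm38 build to reach these counts. The annotation release and the strand setting of the counting are not given in the sources used here. Samples were assigned to groups from their titles. The library descriptions carry a different number for each library without saying what it counts, and no label states that the libraries came from separate litters or days. If the libraries were not from separate animals, the p-values would measure only the spread between these samples, which may be technical.

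The table has 55471 gene identifiers, of which 25742 had a count in at least 1 library, and no entry stands for reads outside genes. Symbols and coordinates came from GENCODE M21 on GRCm38, which matched 55144 identifiers; the 327 without a match held 0.0397% of the counts. Gene totals per library ran from 15973063 to 19437533 counts. Counts of libraries within a group differed beyond sampling noise, with a chi-square per degree of freedom of 4.21 to 7.97 over genes. No library was thus a second copy of another of its group. Pairs across the groups were not compared in this way.

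Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 16052. TMM factors lay between 0.982 and 1.01. Genotypes were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the counts, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 7.48%. CPM values are scaled by the TMM factors, and errors of log2 fold changes are standard errors. Gene lists, 41 in all, were fixed beforehand, covering neuronal, glial, vascular and neighbouring tissue markers, stress responses, metabolism and quality signs. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over the list alone. A list score is the mean log2 CPM of its members in a library. Of the list symbols, 8 were matched through another name of the gene in the RefSeq table, and 3 had no match.

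The rule for named genes took Lhx1os, Lhx1 and passing neighbours of the locus, then up to 12 genes per direction that passed with no overlap between the groups, at a mean of at least 1 CPM. From a called list it took the 4 genes of smallest p, and from another list its passing members or its most abundant ones. Where a direction had fewer than 10 genes, it was filled by smallest p, with those genes stated as not passing. Genes outside the rule are named as chosen after their values were seen, or as passing when adjusted over a list alone. Some genes that the rule selects are not reported here.

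Counts were simulated for the 16052 genes at these library sizes, 3 against 2, with 200 genes changed and all genes varying independently. The edgeR test recovered 65.7% of genes changed by 1.5-fold, 76.1% at 2-fold and 97.0% at 4-fold. Of its 173 calls, 14 (8.09%) were unchanged genes. Real libraries share structure between genes, so recovery in the real data may be lower. The rates also hold only for a simulation with 173 calls. With the 3 calls of the real data the Benjamini-Hochberg adjustment demands a smaller p, so these rates overstate recovery there. In 780 list tests on simulated data without an effect, 4.10% gave p under 0.05, with genes simulated as independent, which real libraries do not meet. Alternatives covered other size factors, other filters, robust dispersion, limma-voom, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, other thresholds and other list tests. A covariate for spinal segment and a covariate for meningeal content were added after the data were seen.

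Some named genes share exon sequence with another gene, and without a stated strand setting their counts are uncertain. These are Plin4 with Hdgfl2 (mean 64.3 CPM), Gpr17 with Lims2 (18.1 CPM), Ina with Nt5c2 (88.4 CPM) and Tuba4a with Stk16 (44.5 CPM), on opposite strands. Hoxc10 with Hoxc5 (12.4 CPM) and Sfpq with Gm12940 (12.8 CPM) lie on the same strand. The tubulin, metallothionein and haemoglobin genes belong to families of similar sequence, among which the counting could divide reads.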

Results

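Messenger RNA was sequenced from the spinal cord of resting male C57BL/6J mice aged 3 months. There were 3 libraries of wild type (WT) mice and 2 of mice carrying a knockout (KO) of Lhx1os. Lhx1os is a long non-coding RNA gene, and the series title ties its loss to motor neuron alterations and impaired locomotion. The KO line was made with Cas9 and a single guide against the second exon of the gene, into which a synthetic polyadenylation signal and a polymerase-destabilising element were inserted to end transcription early. The WT libraries held 17125606, 19437533 and 16086041 counts and the KO libraries 16384033 and 15973063, over 21540 to 21913 genes with a count. Mitochondrially encoded genes took 4.80% to 5.80% of the counts and haemoglobin genes 0.0226% to 0.0340%. Xist had 0 to 2 counts per library and the Y-linked gene Ddx3y 1218 to 1613, as male tissue gives. Correlations between libraries across genes lay between 0.989 and 0.992, and values within and between the genotypes overlapped. The first 3 principal components held 30.6%, 25.2% and 24.8% of the variance, and on the first the genotypes overlapped. On the third they did not, with WT at 17.4, 0.808 and 7.49 and KO at −2.18 and −23.5, where chance parts 2 libraries from 3 in 20% of cases.

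The targeted gene was examined first. Lhx1os (ENSMUSG00000087211), a lincRNA on the plus strand of chromosome 11 from 84525660 to 84535831 in GRCm38, had 56, 66 and 51 counts in the WT libraries and 13 and 11 in the KO libraries. Its level was 3.28 ± 0.124 CPM in WT (SD, n = 3) and 0.742 ± 0.0776 CPM in KO (SD, n = 2), 4.39-fold lower in KO. The log2 fold change was −2.13 (SE 0.28), with an adjusted p of 0.0589 over all genes in edgeR's quasi-likelihood test. Lhx1os thus missed the threshold of 0.05 over all genes, whereas DESeq2 gave an adjusted p of 0.00294, and every KO library lay below every WT library. Gene-level counts do not tell which exons the remaining reads came from. Lhx1 (ENSMUSG00000018698), the neighbouring LIM-homeodomain transcription factor gene on the minus strand from 84518284 to 84525535, starts 124 bases from Lhx1os. Lhx1 stood at 6.35 ± 2.04 CPM in WT and 5.48 ± 0.496 CPM in KO, a log2 fold change of −0.22 (SE 0.25; adjusted p = 0.851), which did not pass. Without WT replicate 2, the library with the most Lhx1 at 8.68 CPM, its log2 fold change was 0.081. None of the 14 tested neighbours of the locus passed over all genes, and 0 passed when adjusted over the list alone. Their most abundant members, Acaca (0.04, SE 0.07) and Synrg (−0.04, SE 0.06), had log2 fold changes within their errors of 0.

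**Figure D1:**
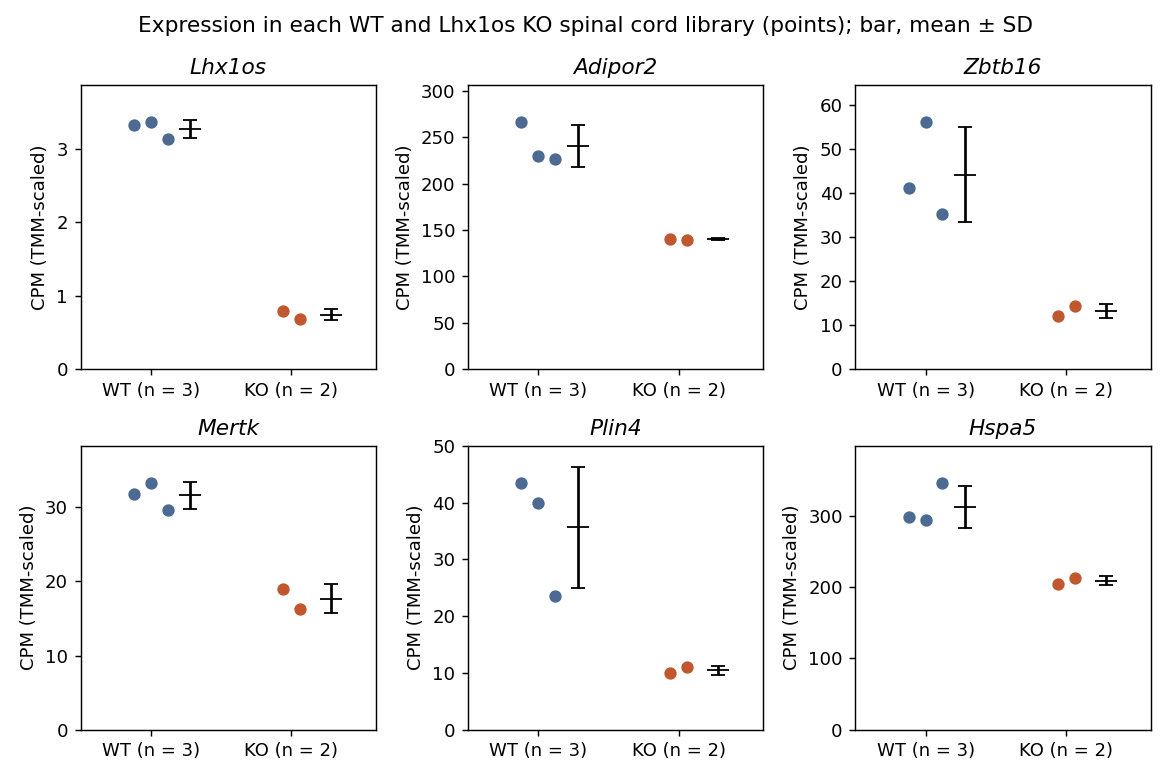
Levels of 6 genes in each library, as TMM-scaled CPM (vertical axes, starting at 0), for 3 WT and 2 Lhx1os KO spinal cord libraries. Points are libraries and bars the mean ± SD. In each panel both KO points lie below all WT points, for example 13 and 11 counts of Lhx1os in KO against 51 to 66 in WT.

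Across the transcriptome, KO spinal cord had lower levels of 3 genes. Zbtb16, which encodes the zinc finger transcription factor PLZF, fell from 44.1 ± 10.8 CPM in WT (SD, n = 3) to 13.1 ± 1.58 CPM in KO (SD, n = 2), with a log2 fold change of −1.76 (SE 0.19). Adipor2, an adiponectin receptor, fell from 240.9 ± 22.4 to 140.2 ± 0.699 CPM (−0.78, SE 0.08). Mertk, a receptor tyrosine kinase used by phagocytes and astrocytes to engulf debris, fell from 31.6 ± 1.86 to 17.6 ± 1.95 CPM (−0.84, SE 0.10). The adjusted p was 0.0223 for Zbtb16 and Adipor2 and 0.0422 for Mertk (edgeR quasi-likelihood test, 16052 genes tested), and each gene was lower in both KO libraries than in all 3 WT libraries. In GRCm38, Zbtb16 lies on chromosome 9 from 48654297 to 48836222, Adipor2 on chromosome 6 from 119353150 to 119417704 and Mertk on chromosome 2 from 128698956 to 128802894. No gene passed as higher in KO. DESeq2 called 40 genes, 37 lower and 3 higher, and limma-voom called 1, Adipor2. Zbtb16 missed the threshold with robust dispersion (adjusted p = 0.167) and Zbtb16 and Mertk with limma-voom (adjusted p = 0.0814), and with a covariate for spinal segment, added after the data were seen, edgeR called 0 genes. Under that covariate the log2 fold changes were −1.69 for Zbtb16, −0.80 for Mertk and −0.77 for Adipor2, each at an adjusted p of 0.0514 with fewer residual degrees of freedom. With 1 KO library left the calls were lost while the fold changes stayed similar: without KO replicate 1 edgeR called 0 genes, and without KO replicate 2 it called 3, of which 0 were these. The log2 fold changes without KO replicates 1 and 2 were −1.64 and −1.89 for Zbtb16, −0.79 and −0.78 for Adipor2 and −0.96 and −0.73 for Mertk. Without WT replicate 2 it called 1, and with WT replicates 1 or 3 left out it called 58 and 10, each including all 3.

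Further genes of small p-value did not reach an adjusted p of 0.05 in edgeR as set out before the data were examined. At an adjusted p under 0.1 there were 15 genes, all lower in KO, and at an unadjusted p under 0.05 there were 1215, with 561 higher and 654 lower against 803 expected by chance. Of the 9 other splits of the 5 libraries into 3 and 2, those of WT replicates 1 and 3 (1560) and WT replicates 2 and 3 (1266) against the rest gave more genes than these 1215. Both splits keep the KO libraries together on the same side, so they carry part of the genotype difference. Plin4, a lipid droplet coat protein, had a log2 fold change of −1.77 (SE 0.23; adjusted p = 0.0589), from 35.7 ± 10.7 CPM in WT to 10.5 ± 0.754 CPM in KO. Hspa5, the chief chaperone of the endoplasmic reticulum (ER), stood at −0.58 (SE 0.08; adjusted p = 0.0589), from 312.3 ± 29.3 to 208.8 ± 6.18 CPM. Gpr17, a receptor of differentiating oligodendrocyte precursors, stood at −0.62 (SE 0.09), Klf9, a Krüppel-like transcription factor, at −0.49 (SE 0.07) and Bcl2l1, the gene of the anti-apoptotic protein Bcl-xL, at −0.41 (SE 0.06), each with an adjusted p of 0.0603. Sfpq, an RNA-binding protein of paraspeckles, had a log2 fold change of −0.44 (SE 0.06; adjusted p = 0.0694). DESeq2 called all 6 of these lower genes, with adjusted p-values from 5.34e-09 for Hspa5 to 0.000719 for Plin4. Robust dispersion in edgeR called each but Plin4, with adjusted p-values from 0.0257 for Hspa5, Gpr17 and Klf9 to 0.0299 for Bcl2l1 and Sfpq. Genes of small p-value on the higher side included Fam222a (0.80, SE 0.14; adjusted p = 0.158) and the immediate early gene Jun (0.47, SE 0.09; adjusted p = 0.192). Both were among the 3 genes that DESeq2 called as higher. Unc5b (0.32, SE 0.06), Creb5 (0.57, SE 0.11), Cdc42ep1 (0.35, SE 0.07), Kif21b (0.32, SE 0.07), Opalin (0.40, SE 0.09), Sox9 (0.39, SE 0.09) and Plekho2 (0.38, SE 0.09) followed on the higher side, with adjusted p-values from 0.193 for Unc5b to 0.320 for Plekho2. The groups did not overlap for 3995 genes, 24.9% of those tested, where chance gives 20%.

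Genes induced by glucocorticoid hormones were lower in KO as a group. All 15 measured members of the list had negative log2 fold changes, with a median of −0.49 and a mean of −0.72, and the list fell in limma's camera test (adjusted p = 5.29e-13). With an estimated correlation between members the list had p = 0.0298, and its call over the 39 lists was lost (adjusted p = 0.930 with an estimated correlation; fry, adjusted p = 0.362). Zbtb16 was the 1 member to pass over all genes in edgeR, where robust dispersion passed Klf9 in its place, and DESeq2 passed 7, Zbtb16, Klf9, Plin4, Arrdc2, Cdkn1a, Tsc22d3 and Map3k6. In edgeR 13 members passed when adjusted over the list alone, Mt1 and Nfkbia being the exceptions. Cdkn1a, the gene of the cell cycle inhibitor p21, had a log2 fold change of −0.51 (SE 0.09). Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at −0.46 (SE 0.13), Tsc22d3, which encodes GILZ, at −0.34 (SE 0.08) and the kinase gene Sgk1 at −1.18 (SE 0.32); these 3 were singled out after their values were seen. The KO libraries lay far apart for Sgk1, at 91.7 ± 58.0 CPM against 208.3 ± 44.4 CPM in WT, and its log2 fold change was −0.65 without KO replicate 1 and −2.04 without KO replicate 2. The number of members passing when adjusted over the list alone stayed between 10 and 14 under every alternative tried.

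The ER chaperone and ER-associated degradation (ERAD) list also fell. Of its 32 measured members 28 were lower in KO, with a median log2 fold change of −0.13 and a mean of −0.18 (camera, adjusted p = 6.72e-09). The camera call was lost when the correlation was estimated (adjusted p = 0.930 with an estimated correlation; fry, adjusted p = 0.410). In edgeR 0 members passed over all genes and 14, all lower, when adjusted over the list alone. Over all genes DESeq2 and edgeR with robust dispersion each passed 2, Hspa5 and Xbp1, and edgeR with DESeq2 size factors passed Hspa5. Those passing when adjusted over the list alone included, beside Hspa5, Xbp1, a transcription factor of the unfolded protein response (−0.54, SE 0.09), the disulphide isomerase gene Pdia4 (−0.37, SE 0.08) and Herpud1 (−0.34, SE 0.08), a component of ERAD. The 14 members became 6 without WT replicate 3, 2 without KO replicate 1 and 5 without KO replicate 2, and 6 with a covariate for meningeal content added after the data were seen. The list of ATF4 targets and the integrated stress response, another arm of the response to ER stress, was not called (camera, adjusted p = 0.944), with 12 members higher and 12 lower and 0 passing when adjusted over the list alone. The cytosolic heat shock list was not called either (adjusted p = 0.148; 11 of 14 lower), and Chordc1 was its 1 member passing when adjusted over the list alone.

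**Figure D2:**
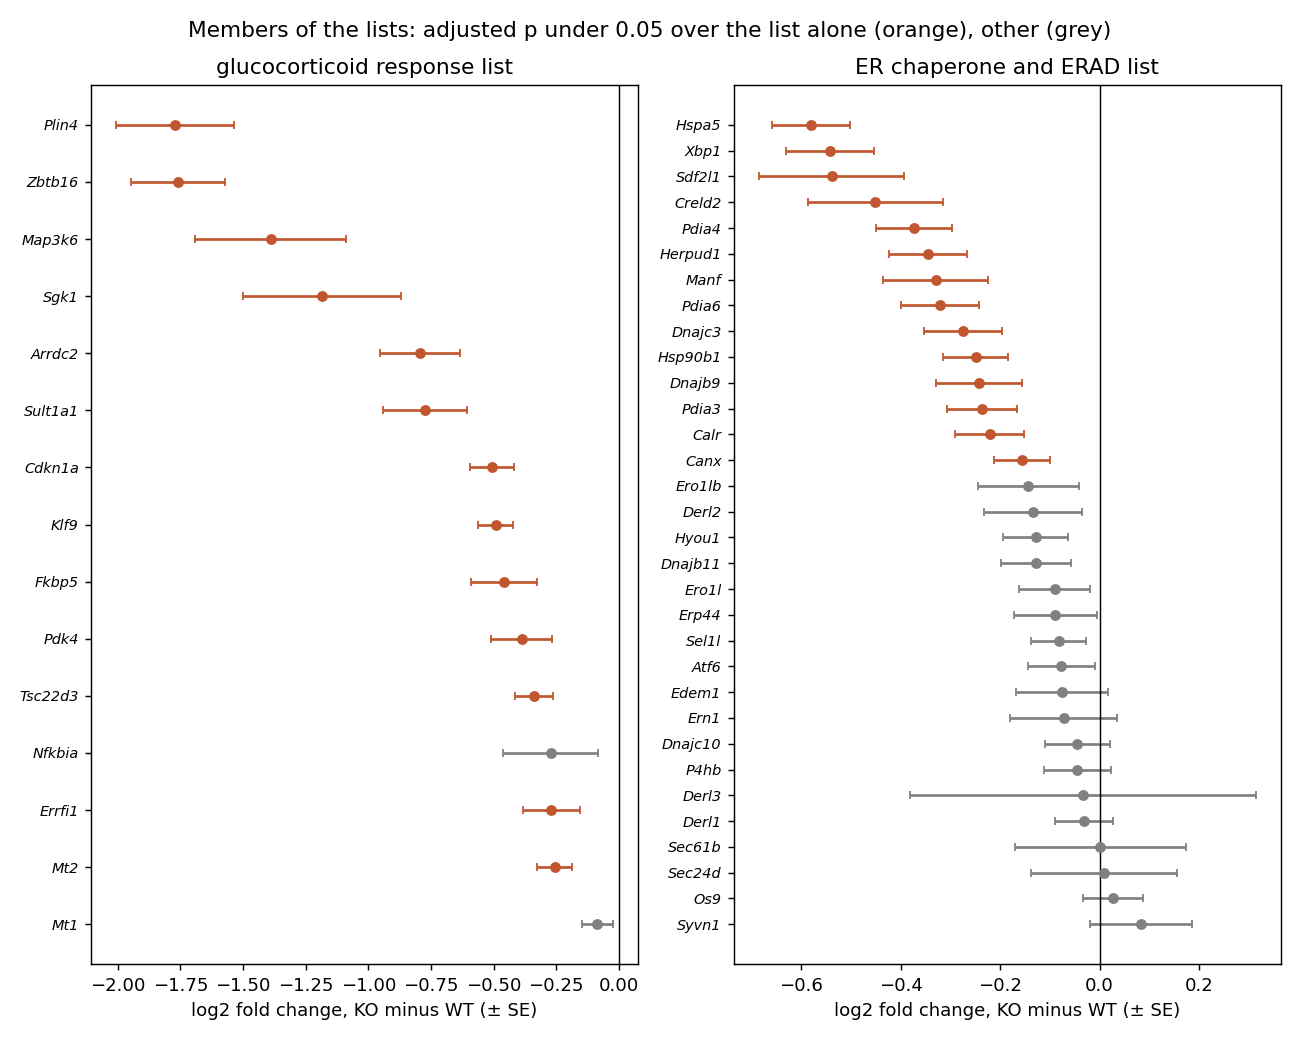
Log2 fold change, KO minus WT, of each measured gene of the glucocorticoid response list (left, 15 genes) and of the ER chaperone and ERAD list (right, 32 genes); points are edgeR estimates from 3 WT and 2 KO libraries and bars ± SE. Orange marks the 13 and 14 genes that passed when adjusted over the list alone, all of them left of 0.

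The oligodendrocyte precursor list fell (camera, adjusted p = 0.0206; adjusted p = 0.930 with an estimated correlation), with 10 of 14 members lower and a median of −0.17. In edgeR 0 passed over all genes, and Gpr17, Neu4 (−0.46, SE 0.11) and Ptprz1 (−0.20, SE 0.06) passed when adjusted over the list alone, while the precursor receptor gene Pdgfra (−0.22, SE 0.08) did not. DESeq2 and edgeR with robust dispersion passed Gpr17 over all genes. The precursor list was no longer called without WT replicate 2 (adjusted p = 0.0809) or KO replicate 2 (adjusted p = 0.212). Mertk was the 1 of 18 homeostatic microglia genes to pass, over all genes and when adjusted over the list alone, and that list was not called (adjusted p = 0.0709). In the astrocyte list (adjusted p = 0.555), the connexin gene Gjb6 was lower (−0.35, SE 0.06) and Sox9 higher when adjusted over the list alone, and DESeq2 passed Gjb6 over all genes. The astrocyte cytoskeletal gene Gfap, in the reactive astrocyte list (adjusted p = 0.150), had a log2 fold change of −0.12 (SE 0.08). The mature oligodendrocyte and myelin list was not called (adjusted p = 0.789), and Opalin passed as higher when adjusted over the list alone.

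Genes of motor neurons, the cells named in the series title, did not pass. Of the 24 motor neuron and cholinergic genes 17 were higher in KO (median log2 fold change 0.12; camera, adjusted p = 0.148; adjusted p = 0.974 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. The acetylcholinesterase gene Ache stood at 0.20 (SE 0.07), Uchl1 at 0.07 (SE 0.06) and the choline acetyltransferase gene Chat, singled out after its value was seen, at 0.15 (SE 0.19). The mean score of the list differed between KO and WT by 0.12 (SE 0.21) on the log2 scale, within the spread between libraries. The neurofilament and axon cytoskeleton list rose (camera, adjusted p = 0.0190; adjusted p = 0.974 with an estimated correlation), with 12 of 14 members higher and 0 passing over all genes or when adjusted over the list alone. WT replicate 1, with a score of 0.13 relative to the WT mean, lay above KO replicate 2 at 0.08. The smallest p-values of the list belonged to the tubulin genes Tubb3 (0.22, SE 0.07), Tuba4a (0.15, SE 0.06) and Tubb2a (0.13, SE 0.06) and to Ina (0.13, SE 0.07), and the call was lost without WT replicate 2 (adjusted p = 0.0696), WT replicate 3 (adjusted p = 0.213) or KO replicate 1 (adjusted p = 0.203).

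Cholesterol synthesis genes rose as a list (camera, adjusted p = 0.0190; adjusted p = 0.974 with an estimated correlation), with 13 of 19 members higher and a median log2 fold change of 0.08. In edgeR 0 passed over all genes and 2, both higher, when adjusted over the list alone, and DESeq2 passed 1 over all genes. These included Insig1 (0.25, SE 0.07), a regulator of sterol sensing in the ER, while the pathway enzyme gene Mvd (0.25, SE 0.09) did not pass. The list was no longer called without WT replicate 2 (adjusted p = 0.380) or KO replicate 1 (adjusted p = 0.221).

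A further 3 lists were called by camera, and none of their members passed over all genes or when adjusted over the list alone. The meningeal fibroblast list fell, with 20 of 20 members lower, among them Mgp (−0.45, SE 0.13), Ccn3 (−0.58, SE 0.24), Fmod (−0.81, SE 0.38) and Foxc1 (−0.45, SE 0.22) (camera, adjusted p = 0.00658; adjusted p = 0.974 with an estimated correlation). Its score relative to the WT mean was −0.68, 0.19 and 0.49 in the WT libraries and −0.40 and −0.28 in the KO libraries, and the call was lost without WT replicate 2 (adjusted p = 0.0639), WT replicate 3 (adjusted p = 0.304) or KO replicate 1 (adjusted p = 0.0683). The interferon response list rose, with 17 of 17 members higher, such as Rsad2 (1.21, SE 0.42) and Ifit3 (0.67, SE 0.25) (adjusted p = 0.0206; adjusted p = 0.974 with an estimated correlation). Its score was 0.74 in KO replicate 1 and −0.15 in KO replicate 2, and without KO replicate 1 the direction turned (adjusted p = 0.257); the call was also lost without WT replicate 1 (adjusted p = 0.187) or WT replicate 2 (adjusted p = 0.0854). The skeletal muscle list rose, with 10 of 10 members higher, such as Myh4 (2.36, SE 0.82), Ckm (1.54, SE 0.73), Acta1 (0.80, SE 0.39) and Actn3 (0.60, SE 0.30) (adjusted p = 0.00330; adjusted p = 0.974 with an estimated correlation). Myh4 reached 0.491 ± 0.446 CPM in WT and 2.55 ± 2.81 CPM in KO, and the muscle call was lost without KO replicate 1 (adjusted p = 0.196).

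**Figure D3:**
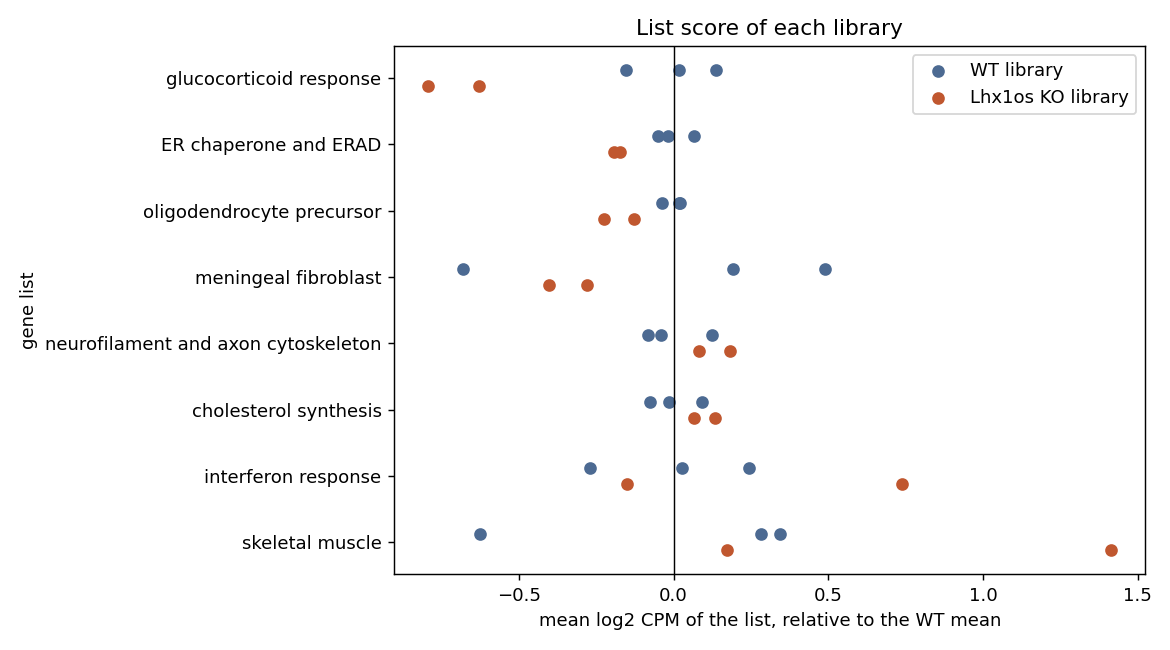
Mean log2 CPM of the members of the 8 called lists in each library, relative to the WT mean (horizontal axis); each point is 1 library, 3 WT and 2 KO. Both KO libraries lie below all WT libraries for the glucocorticoid response (−0.79 and −0.63), ER chaperone and ERAD (−0.17 and −0.19) and oligodendrocyte precursor lists. The groups overlap for the other lists. Chance parts 2 libraries from 3 in 20% of cases.

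The count of 8 called lists did not set the genotypes apart from other groupings: 8 of the 9 other splits of the libraries called more, 11 to 18. Those of the other splits with both KO libraries on the same side are not free of the genotype difference. The remaining 31 of the 39 lists tested were not called by camera (adjusted p from 0.0596 to 0.949), and in 23 of them 0 members passed when adjusted over the list alone. Those with no such member included the synaptic vesicle, inhibitory and excitatory interneuron, proteasome, motor neuron disease gene, activated microglia, pericyte, ependymal, sensory ganglion, adipocyte, erythroid, leukocyte and antigen presentation lists. They also included the oxidative phosphorylation, mitochondrially encoded, ribosomal protein, rostral Hox, extracellular matrix and motor output ion channel lists. Members passing when adjusted over the list alone were lower Slc2a1, a glucose transporter gene (−0.47, SE 0.10), in the endothelial list, which DESeq2 passed over all genes, and lower Cdh19 in the Schwann cell list. In the circadian clock list Per2 (−0.48, SE 0.11), Nr1d2 (−0.21, SE 0.06) and Bhlhe41 (−0.24, SE 0.07) passed as lower when adjusted over the list alone, with 10 of 17 members lower and no call of the list (adjusted p = 0.157). Jun was the 1 immediate early gene to pass when adjusted over the list alone. Median, mean and test differed in sign for the inhibitory interneuron, leukocyte, endothelial, locus neighbour, ATF4 and erythroid lists. The non-polyadenylated RNA and caudal Hox lists had fewer than 5 measured genes and were not tested. With an estimated correlation 0 of the 39 lists passed, as with fry, whose smallest adjusted p was 0.362; fry's test for change in either direction passed 5, among them the glucocorticoid, oligodendrocyte precursor and astrocyte lists.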

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

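The segment and meninges covariates were tests chosen after the results were seen; the other alternatives were not. The count of 3 called genes (0 higher, 3 lower) became 6 with DESeq2 size factors (all lower), 96 with no low-count filter (14 higher, 82 lower), 12 with robust dispersion (all lower), 1 with limma-voom (lower) and 40 with DESeq2's Wald test (3 higher, 37 lower). It was 15, all lower, at an adjusted p under 0.1 and 1 at an absolute log2 fold change of 1 or more. With the meninges covariate it was 8, all lower and including the 3, and with the segment covariate it was 0 (1224 at an unadjusted p under 0.05); there Zbtb16 (−1.69), Mertk (−0.80) and Adipor2 (−0.77) kept their size at an adjusted p of 0.0514, the fit having one residual degree of freedom fewer. Leaving out 1 library gave 0 to 58 calls, 0 to 5 higher and 0 to 53 lower: 58 without WT replicate 1, 1 without WT replicate 2, 10 without WT replicate 3, 0 without KO replicate 1 and 3 without KO replicate 2, a lone library being assumed to vary like the rest. Upper-quartile factors, library totals and a filter of CPM over 1 in 2 libraries gave 3, the same genes. Why these counts moved was not tested.

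With the replicate number as a replicate block the count was 25 (1 higher, 24 lower), including the 3. That fit left only 1 residual degree of freedom. WT replicate 3, alone in its block, added nothing to the genotype difference, so the larger count is not stronger evidence. The block ended the calls of the neurofilament (adjusted p = 0.0636) and meningeal (0.106) lists and of no other. WT and KO share only a number: deviations from the group means correlated at 0.0579 for number 1 and 0.00200 for number 2, with 2 pairs. The deviations of the 2 KO libraries mirror each other, so these values are not separate evidence. WT replicate 3 with KO replicate 2, which share no number, gave 0.0620.

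The log2 fold change of Lhx1os stayed between −2.25 and −2.03 with 1 library left out. It passed the threshold with DESeq2 size factors (−2.14), without the filter (−2.14), with robust dispersion (−2.13), in DESeq2's Wald test (−2.15), with the replicate block (−2.16) and without WT replicate 1; the adjusted p over its alternatives ran from 0.000160 to 0.386.

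The count of 8 called lists became 0 with an estimated correlation, 0 with fry and 8 to 14 with 1 library left out (14 without WT replicate 1), not always the same lists: all but the glucocorticoid and ER lists lost their call without at least 1 library. The adjusted p of the glucocorticoid list was 0.930 with an estimated correlation and 0.362 with fry, and that of the ER list 0.930 and 0.410; both lists were called under each other alternative run. Passing ER members numbered 2 to 13 with 1 library left out (6 without WT replicate 3, 2 without KO replicate 1, 5 without KO replicate 2) and 6 with the meninges covariate. The interferon list turned without KO replicate 1 (adjusted p = 0.257; 2.24e-09 to 0.257 with 1 library left out), and the meningeal list turned once its own score was the covariate (0.950), by construction; that covariate also ended the calls of the neurofilament (0.223), cholesterol (0.249) and muscle (0.0584) lists, and the segment covariate that of the precursor list (0.0793).

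Of 941 alternative values for 59 named genes other than Lhx1os, 849 kept direction and side of the threshold, 69 newly passed, 14 no longer passed and 9 changed sign, none of them called; 3 had no value because the gene was filtered out. With 1 library left out, these were Lhx1 (−0.38 to 0.081), Hoxc10 (−1.01 to 1.79), Hoxa10 (−1.37 to 1.87), Chat (−0.20 to 0.44) and Nr3c1 (−0.10 to 0.070), with the sign changed without WT replicate 2 for Lhx1, without KO replicate 2 for both Hox genes, without KO replicate 1 for Chat and without WT replicate 3 or KO replicate 2 for Nr3c1. The others were Hoxa10 with the segment covariate (−0.15) and Nr3c1 with the replicate block (0.053) and the meninges covariate (0.0036). The cause was not tested. Depth limits genes near the 11 to 13 counts of Lhx1os in KO.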

Other observations

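All tests weighed here were fixed before their results were seen, apart from the segment and meninges covariates. Libraries of one genotype differed in the genes that mark position along the cord. The lumbar Hox gene Hoxc10 stood at 6.01, 5.57 and 17.7 CPM in WT replicates 1, 2 and 3 and at 4.78 and 33.3 CPM in KO replicates 1 and 2, and Hoxa10 at 3.03, 1.38, 9.60, 1.78 and 14.3 CPM in the same order. Splitting the 5 libraries into WT replicate 3 with KO replicate 2 against the rest called 4 genes, Hoxa10, Hoxc10, Hoxc5 and Hoxa9, 1 more than the genotype split did. A difference in the stretch of cord sampled is a candidate source of this pattern. With a covariate for it, 0 genes were called by genotype. The log2 fold changes were then −1.69 for Zbtb16, −0.80 for Mertk and −0.77 for Adipor2, each at an adjusted p of 0.0514 (edgeR quasi-likelihood test).

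WT libraries also differed in meningeal genes. The split of WT replicates 2 and 3 against the other libraries called 38 genes, against 3 for the real split, which points to a structure of the samples. Both KO libraries lie on the same side of that split, so it is not free of the genotype difference. Of these 38, 8 belong to the meningeal fibroblast list, among them Fmod, at 79.8 ± 42.2 CPM in WT (SD, n = 3), and 2, Nefh and Nefm, to the neurofilament and axon cytoskeleton list. Of the 10 splits into 3 and 2 libraries, 3 gave as many called genes as the genotypes, the real one included, and 10 splits are too few for a share under 0.05.

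The lower glucocorticoid response list was weighed against 2 explanations. A shift of the circadian clock at collection that moves the clock phase score by 0.5, the bound set in advance, was argued against. The score differed by −0.0302 (SE 0.0981) between KO and WT on the log2 scale. The bound was not tied to a length of time, so a smaller shift stays open. Per2, and Nr1d2 and Bhlhe41 from the score itself, were lower when adjusted over their list alone. A lower share of oligodendrocyte precursors was argued against as well. Their score (−0.18), the lowest of 6 glial and vascular marker scores, lay 0.534 (SE 0.151) above the glucocorticoid score (−0.71, SE 0.12). Only this lowest score was compared with the list. The endothelial (0.0071, SE 0.315) and pericyte (−0.0555, SE 0.294) scores varied more between libraries. Relative to the WT mean they were 0.37 and 0.24 in KO replicate 1 and −0.35 and −0.35 in KO replicate 2. The glucocorticoid score was low in both KO libraries (−0.79 and −0.63). A lower share of vascular cells was thus not seen in KO replicate 1, and it stays open for KO replicate 2. The real split gave the smallest camera p of the 10 (1 of 10; 1.36e-14 against 4.21e-13 for WT replicates 1 and 2 against the rest), and 10 splits are too few for a share under 0.05. The split of WT replicates 1 and 2 keeps both KO libraries on the same side, so it carries the genotype difference with its sign turned. Its mean log2 fold change for the list was 0.57, against −0.72 in the real split. The list was singled out for its small camera p in the real split, which favours that split in the ranking. The glucocorticoid receptor gene Nr3c1, looked at afterwards, had a log2 fold change of −0.01 (SE 0.08); an effect of genotype and a difference in handling or housing both stay open, and neither was tested.

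The lower ER chaperone and ERAD list was weighed against 3 explanations, none of which the values excluded. The oligodendrocyte precursor score fell about as far as the ER score, with a gap of 0.00570 (SE 0.0422), so fewer precursors were not excluded. Falls of equal size do not show that precursors contribute, because whole tissue does not tell which cells the ER transcripts came from. The motor neuron score did not fall in KO (KO minus WT 0.12, SE 0.21). It lay 0.302 (SE 0.237) above the ER score, by less than 2 SE, so by that rule loss of motor neurons was not excluded and stays open. Relative to the WT mean the motor neuron score was 0.26, −0.11 and −0.15 in WT and 0.29 and −0.05 in KO. Both KO libraries thus lay above WT replicates 2 and 3, whereas for the ER score both lay below every WT library. A general fall of chaperones stays open too, the cytosolic heat shock score lying 0.0789 (SE 0.154) above the ER score. Relative to the WT mean the heat shock score was −0.23 in KO replicate 1 and 0.02 in KO replicate 2, against ER scores of −0.17 and −0.19. The real split again gave the smallest camera p (1 of 10; 3.45e-10 against 1.17e-06 for WT replicates 2 and 3 against the rest), with too few splits for a share under 0.05, and an effect of genotype also remains open. The split of WT replicates 2 and 3 also keeps both KO libraries on the same side, so it is not free of the genotype difference. The ER list, too, was singled out for its small camera p in the real split, which favours that split in the ranking.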
